A study of Mus musculus with 9 samples.

How the data were processed

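The values are expected counts per gene, deposited by the authors as 1 file per library beside FPKM values, and the unit is taken per the labels and the column names. Expected counts share reads that match several genes or transcripts among them, so between 9.77% and 11.0% of the genes in a library had a count that was not a whole number. The counts were rounded to whole numbers. Per the labels, RNA was extracted from the aorta with TRIzol and made into libraries with the MGIEasy mRNA kit from 1.0 ug of total RNA. Per the submitters' processing notes, HISAT2 2.2.1, Bowtie2 2.4.5 and RSEM 1.3.1 were used with the mouse genome build GRCm38.p6. Which of the aligners gave the counts, and the strandedness of the libraries, are not given in the sources used here. The 3 libraries of each group are treated as separate animals, although the labels do not state that they are. The replicate numbers are not treated as pairs.

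The files list 18830 genes, of which 18775 were matched to a symbol and position in the GRCm38.p6 annotation and 55 were not. Counts were 0 in all 9 libraries for 631 genes. After filterByExpr of edgeR with the 3 groups, 14741 genes were tested. Libraries were scaled by TMM (trimmed mean of M values), and CPM are counts per library brought to a common total by these factors. edgeR's quasi-likelihood model (glmQLFit with robust dispersion) was fitted to all 9 libraries with 1 coefficient per group. Each of its 3 comparisons was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes of genes are those of edgeR with its default prior count, and folds of genes near 0 CPM depend on it. The SE beside a log2 fold change is the fold change over the square root of edgeR's F statistic. The common dispersion was 0.263, which is a biological coefficient of variation of 51.3%. The median prior degrees of freedom were 2.10. Exact permutation of 3 libraries against 3 cannot give a two-sided p under 0.1, so no single-gene value was tested that way.

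Gene lists were written from general knowledge of the tissue before the data were examined, as were the design, the thresholds, the planned settings and the rule for naming genes. There were 30 lists, and 29 had at least 5 tested members. The adrenal gland list had 3 tested members and was not tested. Each list was tested against all other genes by limma's camera on log2 CPM (prior count 2), with a preset correlation between genes of 0.01, and adjusted over the 29 lists in each comparison. A list is said to have risen or fallen where that adjusted p is under 0.05. The same test with a correlation estimated per list is given beside it, and limma's fry is given as the lists it called in each comparison. fry asks whether a list's genes move, on balance, one way, and does not compare the list with other genes. A list's value is the mean log2 fold change of its tested members on the log2 CPM scale. Members were also adjusted over the list alone. A gene is said to have risen or fallen where that adjustment passed, and otherwise only its values are given.

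The rule for naming genes had 3 parts. The first took, among genes past the threshold with groups that do not overlap and a mean of at least 10 CPM, the 6 with the largest log2 fold change each way. The next took up to 4 members past the threshold of each list that was called. These parts named 0 genes, since no gene passed. The last part named 20 fixed genes whatever their values. Every other gene in the text was chosen after its values were seen. These are the 10 with the smallest p in each comparison, the 4 members of each list with the smallest p, the genes that the first part picks from the DESeq2 calls, and others picked by hand, among them markers of other tissues.

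A self-test used simulated counts for 14594 genes with the real library sizes and the dispersion of each gene. At 2-, 4-, 8- and 16-fold, edgeR called 6%, 48%, 76% and 84% of the changed genes in a simulated comparison of 14 days with sham, and 0%, 34%, 66% and 84% for 28 days. DESeq2 called 26%, 68%, 86% and 88%, and 8%, 64%, 82% and 94%. Among unchanged genes, edgeR called 3 and 2 and DESeq2 called 65 and 61. All 3 simulated lists that were moved were called and 0 of the others. The simulated genes vary independently of each other, while the correlation estimated within the real lists ran from 0.11 to 0.94. The self-test therefore says nothing on false calls of lists whose genes move together. In 3 simulated sets with no change, edgeR called at most 2, 1 and 0 genes in the 3 comparisons, and DESeq2 called 30 to 45, 23 to 30 and 14 to 28.

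The planned settings were DESeq2, median-of-ratios factors (RLE) in place of TMM, no filter on low counts, a filter of at least 5 CPM in 3 libraries, a log2 fold change of at least 1, the replicate number as a block, fits of the 2 compared groups alone, and each library left out. A planned limma fit to the FPKM values was not run. limma-voom, the nerve list as a covariate, and fits without the 2 libraries rich in skeletal muscle transcripts or without the 3 rich in nerve transcripts were added after the data had been seen. The former leaves 1 library at 28 days, which is assumed to vary like the other groups, so its 28-day values are given without reading a call from them. The latter leaves 2 libraries per group. The median log2 fold change of all genes was -0.07, -0.08 and -0.05 under TMM, for 14 days against sham, 28 days against sham and 28 against 14 days, and -0.05, -0.08 and -0.06 under RLE. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Limits drawn from a count of 0 cover counting error only, since reads without molecular identifiers are not independent molecules.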

Results

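RNA of suprarenal abdominal aortas from ApoE-knockout mice, a strain prone to atherosclerosis, was sequenced in 9 libraries. The 3 groups of 3 libraries were a sham control and mice that received angiotensin II (Ang II), a vasoconstrictor peptide used to induce abdominal aortic aneurysm in mice, at 1000 ng/kg/min by osmotic pump for 14 or 28 days. The labels do not give the day at which the sham aortas were taken. Sham replicates 1 to 3 had 9999430, 13564489 and 12313141 expected counts in total. The totals were 13569092, 14923936 and 14286805 at 14 days and 9609690, 11990870 and 13050368 at 28 days. Values in CPM are means ± SD of 3 libraries per group unless a library is named, and log2 fold changes are given ± SE.

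Apoe, which encodes apolipoprotein E and is the gene targeted in the strain, was read in all 9 libraries (Entrez 11816, ENSMUSG00000002985, GRCm38.p6 chromosome 7, 19696244 to 19701310). It had 22.5, 87.4 and 70.3 CPM in sham replicates 1 to 3, 162, 648 and 160 CPM at 14 days, and 23, 171 and 270 CPM at 28 days. The files hold counts per gene, so the part of Apoe that the reads cover is not known.

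Transcripts of tissues beside the aortic wall differed between libraries of 1 group. The mean level of the nerve, ganglion and Schwann cell list was 3.94, 8.18 and 1.22 log2 CPM in sham replicates 1 to 3, 7.20, 1.70 and 4.71 at 14 days, and 2.22, 7.19 and 6.24 at 28 days. Dbh, whose product makes noradrenaline in sympathetic neurons, had 1754 CPM in sham replicate 2 and a count of 0 in sham replicate 3, which allows up to 0.267 CPM (3 counts) (Entrez 13166, chromosome 2, 27165507 to 27183204). The skeletal muscle list lay between -0.75 and 0.44 log2 CPM in the 6 sham and 14-day libraries and at 9.21, 7.87 and 2.33 in 28-day replicates 1 to 3. Myh4, a myosin of fast skeletal muscle fibres, had a count of 0 in those 6 libraries, which allows at most 0.319 CPM, and 669, 332 and 1.67 CPM in the 28-day libraries (Entrez 17884, chromosome 11, 67237812 to 67260447). The brown fat list lay between 7.31 and 8.40 log2 CPM in sham, between 5.43 and 6.45 at 14 days, and between 6.28 and 7.69 at 28 days. The first 3 principal components held 42.5%, 26.1% and 11.4% of the variance of log2 CPM.

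**Figure D1:**
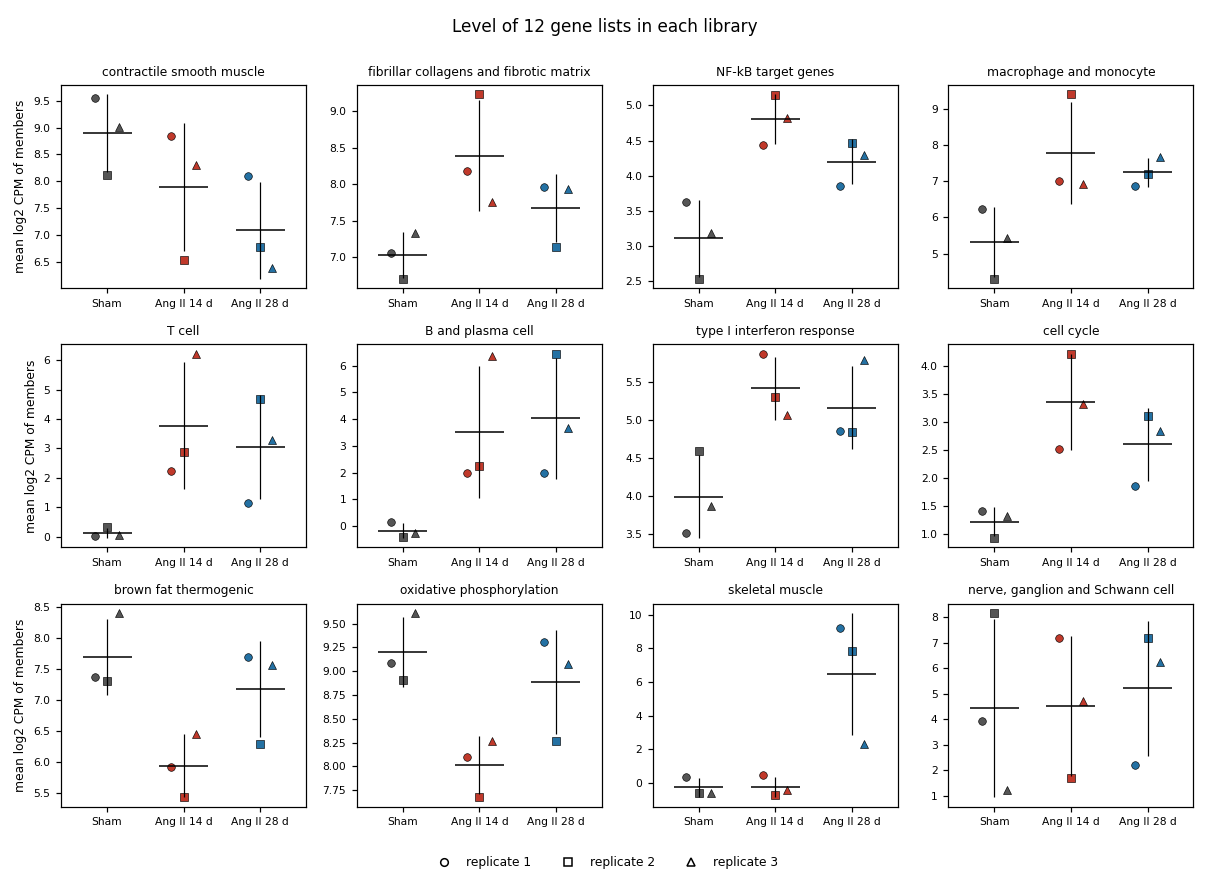
Mean level (log2 CPM) of the members of 12 fixed gene lists in each of the 9 libraries, with the mean ± SD of 3 libraries per group. The skeletal muscle list reaches 9.21 and 7.87 in 28-day replicates 1 and 2, and the nerve list runs from 1.22 to 8.18 within sham.

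Aortas after 14 days of Ang II were compared with sham aortas to ask which transcripts differ in the course of aneurysm formation, with the NF-kB pathway as a stated interest of the series. Targets of NF-kB, a transcription factor of inflammatory signalling, rose by 1.69 log2 on average (3.23-fold, adjusted p = 3.83e-10, adjusted p = 0.298 with an estimated correlation). Of the 23 members, 19 rose and 1 fell when adjusted over the list alone, and 0 passed over all genes tested. Nfkb1, the p105/p50 subunit itself, rose from 49.3 ± 4.45 to 95.3 ± 22.3 CPM (log2 0.95 ± 0.21; Entrez 18033, ENSMUSG00000028163, chromosome 3, 135584655 to 135691969). Tnf rose from 0.510 ± 0.395 to 4.32 ± 1.52 CPM (8.52-fold; Entrez 21926, chromosome 17, 35199367 to 35202007). The chemokine genes Ccl5, Cxcl10 and Ccl2 rose by 3.54 ± 0.79, 2.87 ± 0.76 and 2.97 ± 0.98 log2, and Cxcl2 from 0.225 ± 0.182 to 2.39 ± 2.55 CPM. Il1b, Traf1, Icam1 and Nfkbia rose by 2.69 ± 0.71, 2.61 ± 0.68, 1.17 ± 0.34 and 0.65 ± 0.21 log2. The member that fell was Sod2, a mitochondrial superoxide dismutase, from 522 ± 190 to 220 ± 52.8 CPM. Rela was not in the list and had 84.8 ± 15.8 CPM in sham and 108 ± 15.8 CPM at 14 days. Il6 did not pass the filter on low counts, with 0.261 ± 0.228 and 3.03 ± 2.49 CPM.

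Leukocyte lists rose with the NF-kB list. The macrophage and monocyte list rose by 2.46 log2 (5.49-fold, adjusted p = 1.38e-10, adjusted p = 0.298 with an estimated correlation), and 19 of 22 members passed over the list alone. Ptprc, the pan-leukocyte antigen CD45, rose from 18.8 ± 5.46 to 204 ± 157 CPM, Adgre1, which encodes F4/80, from 18.4 ± 3.76 to 135 ± 163 CPM, and Cd68 from 68.1 ± 72.7 to 609 ± 753 CPM. Cd68 was at 191, 1478 and 158 CPM in 14-day replicates 1 to 3, against 150 CPM in sham replicate 1. Without 14-day replicate 2 the value of list macrophage and monocyte, Ang II 14 days against sham, was 1.67 log2. Without 14-day replicate 3 that of list MHC class II presentation, Ang II 14 days against sham, was 1.80. The neutrophil list rose by 1.93 log2 (adjusted p = 0.000817, adjusted p = 0.298 with an estimated correlation) with 4 of 6 members, Csf3r and S100a8 among them, and by 1.10 with no filter on low counts. The T cell list rose by 3.66 log2 (12.6-fold, adjusted p = 1.21e-07, adjusted p = 0.328 with an estimated correlation) and the B and plasma cell list by 3.69 log2 (12.9-fold, adjusted p = 1.14e-05, adjusted p = 0.36 with an estimated correlation), each with all members, 13 and 11. Without 14-day replicate 3 these lists rose by 2.43 and 2.27 log2. The B and plasma cell list had a level of 1.97, 2.23 and 6.34 log2 CPM in 14-day replicates 1 to 3, beside 1.92, 0.88 and 4.42 for 8 lymph node stroma and vessel genes, a list written after the data had been seen. Cd3g, part of the T cell receptor complex, rose from 1.34 ± 0.326 to 39.2 ± 47.6 CPM, and Cd79a, part of the B cell receptor, from 1.58 ± 0.621 to 178 ± 286 CPM. The MHC class II list, which serves antigen presentation, rose by 2.46 log2 (adjusted p = 3.41e-08, adjusted p = 0.298 with an estimated correlation) with 10 of 10 members. H2-Aa rose from 219 ± 19.4 to 878 ± 325 CPM (Entrez 14960, chromosome 17, 34282744 to 34287823).

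Interferon-response, inflammasome and cell cycle lists rose at 14 days. The type I interferon list rose by 1.43 log2 (adjusted p = 2.45e-08, adjusted p = 0.298 with an estimated correlation) with 8 of 14 members, among them Irf7, Isg15 and Bst2 at 2.47 ± 0.46, 1.72 ± 0.46 and 1.40 ± 0.29 log2. Oas1a, an antiviral synthetase, rose from 6.95 ± 1.22 to 40.7 ± 11 CPM (log2 2.55 ± 0.33; Entrez 246730, chromosome 5, 120896256 to 120907544). Oas1a was among the 10 genes with the smallest p of the comparison, of which 0 passed over all genes. Of the others, Plac8 was 6.84 ± 2.47 and 46.2 ± 9.60 CPM (adjusted p = 0.112; Entrez 231507, chromosome 5, 100551589 to 100572253), and Phf11b, Trim30a, Ifi47, Zbp1, Slfn2, Tmem176b, Rnf213 and Rtn4rl2 were 2.28 ± 0.26, 1.85 ± 0.22, 1.99 ± 0.26, 2.51 ± 0.33, 3.0 ± 0.40, 1.66 ± 0.22, 1.28 ± 0.17 and 1.66 ± 0.25 log2 higher. Reads of Phf11b, Trim30a, Slfn2, Hbb-bs and the H2 genes can match close paralogs, so their assignment is uncertain. The inflammasome list rose by 1.88 log2 (adjusted p = 2.49e-08, adjusted p = 0.298 with an estimated correlation) with 10 of 11 members, among them the adaptor Pycard at 2.55 ± 0.49, Nlrc4 at 2.87 ± 0.64 and the pore-forming Gsdmd at 1.36 ± 0.29 log2. The cell cycle list rose by 2.14 log2 (4.40-fold, adjusted p = 1.02e-13, adjusted p = 0.298 with an estimated correlation) with 19 of 20 members. Top2a, a topoisomerase of dividing cells, rose from 3.32 ± 0.811 to 27.9 ± 18.1 CPM (Entrez 21973, chromosome 11, 98992947 to 99024199), and Mki67 rose by 3.01 ± 0.61 log2. The red cell and platelet list rose by 1.47 log2 (adjusted p = 0.000123, adjusted p = 0.298 with an estimated correlation) with 7 of 9 members, Hbb-bs among them at 1.85 ± 0.46 log2.

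Matrix genes were higher at 14 days. The list of fibrillar collagens and fibrotic matrix rose by 1.36 log2 (2.56-fold, adjusted p = 8.72e-07, adjusted p = 0.298 with an estimated correlation), and 5 of 20 members passed over the list alone: Col8a1, P4ha3, Fn1, Col12a1 and Lum, at 2.85 ± 0.62, 3.07 ± 0.71, 1.25 ± 0.34, 2.44 ± 0.68 and 2.04 ± 0.58 log2. Fn1, which encodes fibronectin, rose from 1507 ± 143 to 3594 ± 159 CPM (Entrez 14268, chromosome 1, 71585473 to 71653280). Col1a1 was 911 ± 370 and 3523 ± 3000 CPM (Entrez 12842, chromosome 11, 94936224 to 94953042), and Col3a1 was 1.48 ± 0.55 log2 higher. The protease and inhibitor list rose by 1.29 log2 (adjusted p = 8.15e-05, adjusted p = 0.364 with an estimated correlation), and by 0.84 without 14-day replicate 2. Of its 24 members 0 passed over the list alone. Mmp2, Mmp9, Mmp12 and Timp1 were 1.92 ± 0.62, 1.82 ± 0.60, 2.23 ± 1.57 and 2.51 ± 0.82 log2 higher. The TGF-beta list rose by 0.66 log2 (adjusted p = 0.0171, adjusted p = 0.45 with an estimated correlation) with 2 of 16 members. These were Thbs1, whose product activates latent TGF-beta, from 55.8 ± 19.7 to 357 ± 146 CPM (Entrez 21825, chromosome 2, 118111876 to 118127133), and Tgfb1, by 1.75 ± 0.46 log2. The elastic fibre and the adventitial fibroblast lists rose by 0.61 and 0.57 log2 (adjusted p = 0.0171 for each, adjusted p = 0.519 for each with an estimated correlation), with 0 members over the list alone. Eln, which encodes elastin, was 2766 ± 1652 and 3796 ± 721 CPM (Entrez 13717, chromosome 5, 134702595 to 134747368).

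Smooth muscle, fat and mitochondrial lists fell on average. The contractile smooth muscle list fell by 1.0 log2 (2-fold, adjusted p = 0.00125, adjusted p = 0.524 with an estimated correlation), with 19 of 21 members lower and 0 past the threshold over the list alone. Acta2, smooth muscle actin, was 9441 ± 4423 and 5438 ± 3201 CPM (Entrez 11475, ENSMUSG00000035783, chromosome 19, 34240336 to 34255585), and Myh11, smooth muscle myosin, was 3805 ± 1942 and 1592 ± 1199 CPM (Entrez 17880, chromosome 16, 14194527 to 14292188). The oxidative phosphorylation list fell by 1.19 log2 (adjusted p = 1.21e-12, adjusted p = 0.298 with an estimated correlation) with 22 of 22 members, and the fatty acid oxidation list by 1.38 log2 (adjusted p = 8.51e-10, adjusted p = 0.298 with an estimated correlation) with 17 of 18. The brown fat list fell beside them by 1.76 log2 (3.39-fold, adjusted p = 1.62e-06, adjusted p = 0.298 with an estimated correlation) with 7 of 11 members. Ucp1, the uncoupling protein of brown fat, fell from 3794 ± 2041 to 1057 ± 602 CPM (Entrez 22227, chromosome 8, 83290348 to 83298456). Cox7a1, Cox8b, Ndufs1, Hadhb and Ppara fell by 2.53 ± 0.51, 2.05 ± 0.45, 1.35 ± 0.36, 1.73 ± 0.47 and 1.99 ± 0.45 log2. The adipocyte list fell by 0.84 log2 (adjusted p = 0.00459, adjusted p = 0.519 with an estimated correlation) with 0 of 13 members over the list alone.

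In all, 20 of 29 lists passed at 14 days, 15 up and 5 down, and 0 with an estimated correlation (3 at an unadjusted p under 0.05), while fry called 10, 7 up and 3 down (NF-kB, neutrophil, MHC class II, interferon, inflammasome, cell cycle and red cell up, and brown fat, oxidative phosphorylation and fatty acid oxidation down). Other splits of the same 6 libraries into 3 and 3 gave 10 to 20 lists. The count of 20 therefore does not set the real groups apart from other splits. Over the lists alone 175 members passed, and 0 over all genes. edgeR called 0 of 14741 genes (lowest adjusted p = 0.112), with 3460 at an unadjusted p under 0.05 (1931 up, 1529 down) where chance gives 737 on average. Other splits of the same 6 libraries gave up to 2514 such genes. DESeq2 called 1902 (1261 up, 641 down) and limma-voom 0. The groups did not overlap for 26.1% of genes, where chance gives 10%. Lists that did not pass were endothelial (0.23 log2, adjusted p = 0.0903), skeletal muscle (0.02, 0.935), nerve (0.09, 0.791), cartilage and bone (1.06, 0.0549), immediate early (0.988), ER stress (0.35, 0.0549), renin-angiotensin (0.50, 0.348), circadian clock (-0.37, 0.127) and foam cell (0.71, 0.0808). The nerve mean was positive although 12 of its 14 members had negative edgeR folds. Agtr1a, the Ang II receptor, was 62.0 ± 95.5 and 21.3 ± 25.9 CPM (Entrez 11607, chromosome 13, 30336356 to 30382867). The calls depended on single libraries for 5 lists: smooth muscle without 14-day replicate 2 (-0.31, adjusted p = 0.0629), adipocyte without the same library (-0.20, 0.203), elastic fibre without sham replicate 2 (0.35, 0.268), 14-day replicate 1 (0.61, 0.0585) or 14-day replicate 2 (0.42, 0.123), TGF-beta without sham replicate 2 (0.41, 0.347) or 14-day replicate 1 (0.67, 0.0585), and fibroblast without sham replicate 1 (0.44, 0.116), sham replicate 2 (0.43, 0.106) or 14-day replicate 1 (0.42, 0.186), with 0.88 without sham replicate 3.

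Other lists passed at 14 days without 1 library. These were endothelial without sham replicate 3 (0.34, adjusted p = 0.0356), 14-day replicate 2 (0.42, 0.0102) or 28-day replicate 1 (0.23, 0.0434), ER stress without sham replicate 3 (0.40, 0.0307) or 14-day replicate 3 (0.50, 0.00700), and foam cell without sham replicate 3 (0.83, 0.0410) or 14-day replicate 3 (0.93, 0.0183). Cartilage and bone passed without sham replicate 1 (1.28, 0.0454), sham replicate 3 (1.21, 0.0356), 14-day replicate 3 (1.22, 0.0234), 28-day replicate 1 (1.10, 0.0365) or 28-day replicate 2 (1.10, 0.0388). Without sham replicate 2 the nerve (1.96, 0.0166) and circadian clock (-0.68, 0.0217) lists passed, and without 14-day replicate 2 renin-angiotensin did (0.99, 0.0424). Without the 3 nerve-rich libraries (sham replicate 2, 14-day replicate 1 and 28-day replicate 2), elastic fibre (0.39, 0.419), fibroblast (0.32, 0.357) and TGF-beta (0.46, 0.530) did not pass, smooth muscle fell by 1.83 log2, and the circadian clock passed (-0.72, 0.0362). With the replicate block elastic fibre did not pass (adjusted p = 0.0506) and endothelial did (0.0435). Cartilage passed with no filter on low counts (0.0412), and with the nerve list as a covariate cartilage (0.0235) and ER stress (0.0247) passed.

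**Figure D2:**
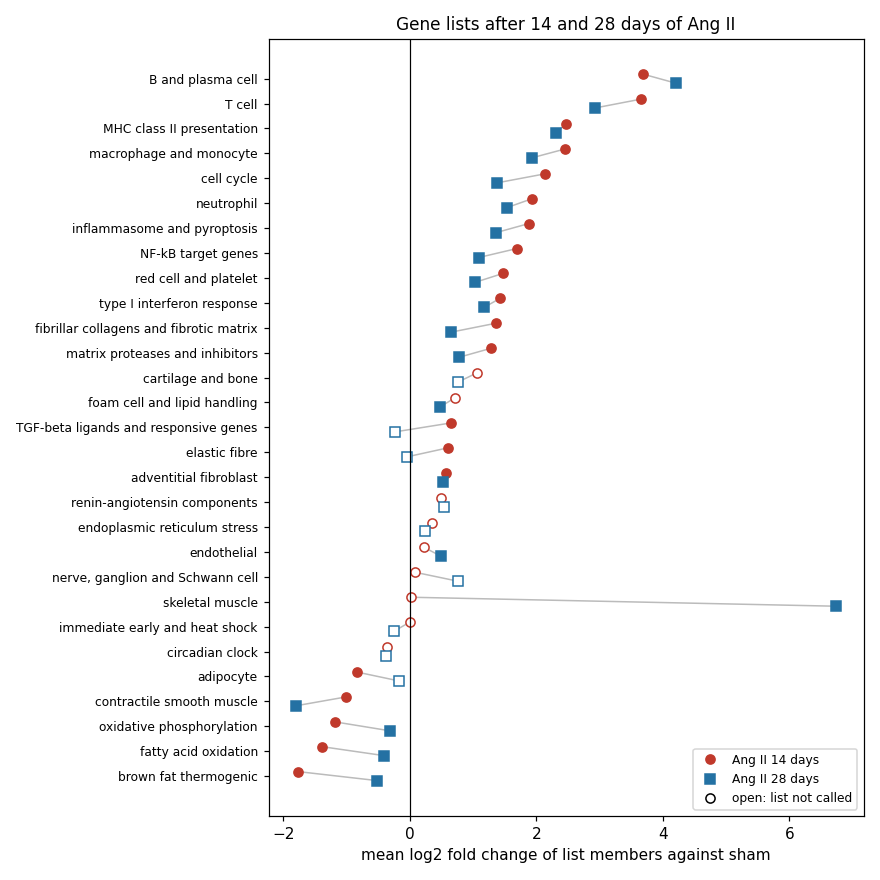
Mean log2 fold change against sham of the members of each of the 29 tested lists, at 14 days (circles) and 28 days (squares), with open symbols for lists that did not pass. The smooth muscle list lies at -1.0 and -1.80, the oxidative phosphorylation list at -1.19 and -0.32, and the NF-kB list at 1.69 and 1.09.

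Aortas after 28 days of Ang II were compared with sham for the same question at the later time. The contractile smooth muscle list fell by 1.80 log2 on average (3.49-fold, adjusted p = 1.10e-09, adjusted p = 0.367 with an estimated correlation), and 13 of 21 members fell over the list alone. Its level was 9.55, 8.12 and 9.02 log2 CPM in sham replicates 1 to 3, and 8.11, 6.78 and 6.39 in 28-day replicates 1 to 3. The level of 28-day replicate 1 thus lay next to that of sham replicate 2. Acta2 fell from 9441 ± 4423 to 1631 ± 1026 CPM (log2 -2.53 ± 0.70) and Myh11 from 3805 ± 1942 to 595 ± 419 CPM (log2 -2.68 ± 0.86). Myocd, a coactivator that drives the smooth muscle program, fell from 69.6 ± 27.4 to 8.57 ± 5.61 CPM (Entrez 214384, chromosome 11, 65173608 to 65269989), and Itga8 from 875 ± 456 to 87.0 ± 47.4 CPM. Tagln, Cnn1, Smtn, Myl9 and Cald1 fell by 2.24 ± 0.72, 2.43 ± 0.83, 2.16 ± 0.60, 2.56 ± 0.72 and 1.55 ± 0.43 log2. The smallest p of the comparison belonged to Myh10, a non-muscle myosin, at 248 ± 55.1 and 69.0 ± 4.50 CPM (log2 -1.85 ± 0.22, adjusted p = 0.203; Entrez 77579, chromosome 11, 68691915 to 68816626). Without sham replicate 2, Myh10 passed over all genes at -2.02 log2 (adjusted p = 0.0289), as it did by DESeq2. Pde3a, Endod1, Pcdh7 and Scube3 were lower by 1.59 ± 0.21, 1.41 ± 0.18, 2.05 ± 0.30 and 3.26 ± 0.50 log2. Eln was 2766 ± 1652 and 872 ± 258 CPM.

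Inflammatory and immune lists stayed above sham at 28 days. The NF-kB list rose by 1.09 log2 (2.13-fold, adjusted p = 3.92e-08, adjusted p = 0.312 with an estimated correlation), and by 0.64 without the 3 nerve-rich libraries, with 0 of 23 members past the threshold over the list alone, 12 at an unadjusted p under 0.05 and 5 by DESeq2. Nfkb1, Tnf, Il1b, Ccl2, Ccl5 and Nfkbia were 0.63 ± 0.21, 2.33 ± 0.73, 1.51 ± 0.69, 1.47 ± 0.93, 2.87 ± 0.77 and 0.64 ± 0.21 log2 higher, and Rela had 87.5 ± 3.08 CPM. The B and plasma cell list rose by 4.20 log2 (18.4-fold, adjusted p = 8.45e-09, adjusted p = 0.326 with an estimated correlation) with 11 of 11 members, and the T cell list by 2.92 log2 (adjusted p = 6.74e-08, adjusted p = 0.367 with an estimated correlation) with 12 of 13. The B and plasma cell list had a level of 1.98, 6.45 and 3.66 log2 CPM in 28-day replicates 1 to 3, beside 2.70, 5.74 and 3.18 for the lymph node stroma and vessel genes, and replicate 2 had 248 CPM of Glycam1 and 69.4 CPM of Cr2, transcripts of lymphoid tissue. Without that library the values were 2.99 for list B and plasma cell, Ang II 28 days against sham, 2.09 for list T cell, Ang II 28 days against sham, and 1.70 for list MHC class II presentation, Ang II 28 days against sham. Jchain, the joining chain of antibodies from plasma cells, rose from 5.99 ± 3.52 to 177 ± 179 CPM. The MHC class II list rose by 2.31 log2 (adjusted p = 6.69e-10, adjusted p = 0.312 with an estimated correlation) with 10 of 10 members. The macrophage list rose by 1.93 log2 (adjusted p = 1.47e-10, adjusted p = 0.326 with an estimated correlation) with 0 of 22 over the list alone, and Cd68 was 219 ± 56.6 CPM. The neutrophil list rose by 1.53 log2 (adjusted p = 0.00195, adjusted p = 0.312 with an estimated correlation) with 3 of 6 members, and did not pass without the 3 nerve-rich libraries (0.99, adjusted p = 0.0555).

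The interferon list rose by 1.18 log2 (adjusted p = 2.28e-09, adjusted p = 0.312 with an estimated correlation) with 5 of 14 members, and Oas1a rose to 25.7 ± 9.79 CPM. Trim30a, Plac8, Ifi205, Parp14 and Ifi47 were 1.64 ± 0.22, 2.31 ± 0.32, 1.65 ± 0.25, 1.02 ± 0.16 and 1.66 ± 0.25 log2 higher, and reads of Ifi205 can match paralogs. The inflammasome list rose by 1.37 log2 (adjusted p = 6.74e-08, adjusted p = 0.312 with an estimated correlation) with 7 of 11 members, Aim2 among them. The cell cycle list rose by 1.39 log2 (adjusted p = 4.09e-11, adjusted p = 0.326 with an estimated correlation) with 11 of 20, and the red cell and platelet list by 1.03 log2 (adjusted p = 0.00103, adjusted p = 0.312 with an estimated correlation) with 2 of 9. The endothelial list rose by 0.50 log2 (adjusted p = 4.03e-05, adjusted p = 0.459 with an estimated correlation) with 4 of 15 members, Cldn5, Robo4, Kdr and Cdh5, and by 0.23 without 28-day replicate 1. Kdr, the VEGF receptor, rose from 82.9 ± 15.9 to 170 ± 49.3 CPM (Entrez 16542, chromosome 5, 75932827 to 75979072).

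The skeletal muscle list rose by 6.74 log2 (adjusted p = 2.06e-15, adjusted p = 0.312 with an estimated correlation) with 15 of 16 members. This mean depends on the prior count of 2, since most members are near 0 in sham, although Ckm, Tnnt1 and Mybpc2 had 36.5, 8.95 and 5.22 CPM in sham replicate 1. Acta1, skeletal actin, had 4696, 1583 and 35.7 CPM in 28-day replicates 1 to 3. In replicate 3 alone, with replicates 1 and 2 left out, the list was 2.61 log2 above sham. The collagen list rose by 0.65 log2 (adjusted p = 0.0490, adjusted p = 0.585 with an estimated correlation), proteases by 0.79 (adjusted p = 0.0224, adjusted p = 0.583 with an estimated correlation), the adventitial fibroblast list by 0.53 (adjusted p = 0.00651, adjusted p = 0.583 with an estimated correlation) and the foam cell list by 0.48 (adjusted p = 0.0490, adjusted p = 0.583 with an estimated correlation). The oxidative phosphorylation, fatty acid oxidation and brown fat lists fell by 0.32, 0.40 and 0.52 log2 (adjusted p = 0.00732, 0.0101 and 0.0490). With an estimated correlation their adjusted p = 0.585, 0.583 and 0.583. None of these 7 lists had a member past the threshold over the list alone. Col1a1, Col3a1, Mmp2, Mmp9, Mmp12, Timp1 and Tgfb1 were 1.16 ± 0.64, 0.95 ± 0.54, 1.54 ± 0.62, 1.93 ± 0.60, 1.01 ± 1.52, 0.78 ± 0.78 and 0.93 ± 0.45 log2 higher.

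In all, 20 of 29 lists passed at 28 days, 16 up and 4 down, and 0 with an estimated correlation (1 at an unadjusted p under 0.05) or by fry. Other splits of the same 6 libraries into 3 and 3 gave 6 to 17 lists. Over the lists alone 93 members passed, and 0 over all genes. edgeR called 0 genes (lowest adjusted p = 0.203), with 2042 at an unadjusted p under 0.05 (1174 up, 868 down) where chance gives 737 on average. Another split of the same 6 libraries gave 2544 such genes, more than the real groups did. DESeq2 called 996 (600 up, 396 down) and limma-voom 0. The groups did not overlap for 21.7% of genes, where chance gives 10%. Lists that did not pass were elastic fibre (-0.04 log2, adjusted p = 0.694), adipocyte (-0.17, 0.694), nerve (0.77, 0.401), cartilage (0.76, 0.216), TGF-beta (-0.23, 0.0748), immediate early (-0.25, 0.223), ER stress (0.145), renin-angiotensin (0.171) and circadian clock (-0.37, 0.119). The nerve mean was positive although 13 of 14 members had negative edgeR folds. Agtr1a was 49.8 ± 35.4 CPM, and Il6 was 0.368 ± 0.262 CPM.

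Of the 20 calls at 28 days, 13 held without each library in turn and 7 did not. The collagens did not pass without sham replicate 1 (0.66, adjusted p = 0.0524), sham replicate 2 (0.48, 0.551), 14-day replicate 1 (0.64, 0.0824), 28-day replicate 1 (0.51, 0.398) or 28-day replicate 3 (0.55, 0.207). Nor did the proteases without sham replicate 2 (0.41, 0.461), 28-day replicate 1 (0.66, 0.241) or 28-day replicate 3 (0.74, 0.108). Fibroblast genes failed without sham replicate 1 (0.40, 0.0674), sham replicate 2 (0.40, 0.0938), 28-day replicate 1 (0.33, 0.123) or 28-day replicate 3 (0.40, 0.0984), and rose by 0.84 without sham replicate 3 and 0.89 without 28-day replicate 2. Brown fat failed without sham replicate 3 (-0.12, 0.474), 14-day replicate 1 (-0.52, 0.0644) or 28-day replicate 2 (-0.07, 0.682). Oxidative phosphorylation failed without sham replicate 3 (-0.06, 0.460) or 28-day replicate 2 (-0.01, 0.882), and fell by 0.53 without 28-day replicate 1. Fatty acid oxidation failed without sham replicate 3 (-0.09, 0.402) or 28-day replicate 2 (-0.09, 0.393). Foam cell genes failed without sham replicate 2 (0.31, 0.352), 14-day replicate 1 (0.47, 0.0712), 14-day replicate 3 (0.47, 0.0522), 28-day replicate 1 (0.53, 0.113) or 28-day replicate 3 (0.36, 0.266).

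Other lists passed at 28 days without 1 library: TGF-beta without sham replicate 2 (-0.48, adjusted p = 0.00562) or 28-day replicate 1 (-0.39, 0.0168), nerve without the same libraries (2.63, 0.00265, and 2.27, 0.0319), immediate early without sham replicate 1 (-0.54, 0.00307) and circadian clock without sham replicate 2 (-0.68, 0.0183). Without the 3 nerve-rich libraries the collagens (0.72, 0.139), proteases (0.57, 0.112), foam cell (0.36, 0.139), brown fat (-0.30, 0.25), oxidative phosphorylation (-0.20, 0.112) and fatty acid oxidation (-0.23, 0.25) did not pass, while TGF-beta (-0.43, 0.0122), nerve (1.62, 0.0104) and renin-angiotensin (0.98, 0.0270) did. The collagens also failed with RLE factors (adjusted p = 0.0520), with no filter on low counts (0.0580) and with the replicate block (0.10), foam cell with no filter (0.0580) and the block (0.0560), proteases with the block (0.0577), and brown fat with the nerve covariate (0.0871). TGF-beta passed with the block (0.0469) and ER stress with the nerve covariate (0.0469). In 28-day replicate 3 alone (n = 1), without the libraries rich in skeletal muscle transcripts, the mean differences from sham were -0.14 for brown fat, -0.13 for oxidative phosphorylation, -0.11 for fatty acid oxidation, -0.39 for TGF-beta, -0.49 for immediate early, 0.24 for endothelial, 0.85 for fibroblast, 0.76 for foam cell, 1.81 for interferon and 1.02 for neutrophil genes.

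The aortas at 28 days were compared with those at 14 days, which is also the test of whether the changes against sham differ between the times. The TGF-beta list fell by 0.89 log2 (adjusted p = 2.68e-09, adjusted p = 0.386 with an estimated correlation), and 0 of its 16 members passed over the list alone. Thbs1 was 357 ± 146 and 124 ± 52.8 CPM, and Inhba was 1.51 ± 0.41 log2 lower. The collagen list fell by 0.71 log2 (adjusted p = 3.05e-06, adjusted p = 0.637 with an estimated correlation), and the members past the threshold over the list alone were Fn1, from 3594 ± 159 to 1262 ± 590 CPM, and Tnc, from 170 ± 58.0 to 71.3 ± 16 CPM. The elastic fibre list fell by 0.64 log2 (adjusted p = 0.000154, adjusted p = 0.637 with an estimated correlation) with 0 of 16 members, and Eln was 3796 ± 721 and 872 ± 258 CPM (log2 -2.12 ± 0.53). The contractile smooth muscle list fell by 0.80 log2 (adjusted p = 0.000327, adjusted p = 0.677 with an estimated correlation), and the protease list by 0.50 (adjusted p = 0.00370, adjusted p = 0.674 with an estimated correlation), each with 0 members past the threshold over the list alone.

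Some inflammatory lists were lower at 28 days than at 14, while the T cell, B and plasma cell, neutrophil, MHC class II and interferon lists did not pass. The NF-kB list fell by 0.60 log2 (adjusted p = 0.00122, adjusted p = 0.637 with an estimated correlation). Cxcl2 was 0.371 ± 0.208 CPM at 28 days, and Ptgs2 was lower by 1.34 ± 0.45 log2. The macrophage list fell by 0.53 (adjusted p = 0.0288, adjusted p = 0.805 with an estimated correlation), the inflammasome list by 0.51 (adjusted p = 0.0176, adjusted p = 0.674 with an estimated correlation), the cell cycle list by 0.75 (adjusted p = 2.10e-06, adjusted p = 0.637 with an estimated correlation) and the red cell and platelet list by 0.44 (adjusted p = 0.0362, adjusted p = 0.637 with an estimated correlation). These 5 lists had 0 members past the threshold over the list alone. Without 14-day replicate 2 the macrophage list rose instead, by 0.29 log2 (adjusted p = 0.0331). Transcript lists of energy metabolism and brown fat moved the other way. The oxidative phosphorylation list rose by 0.87 log2 (adjusted p = 1.91e-17, adjusted p = 0.436 with an estimated correlation), fatty acid oxidation by 0.98 (adjusted p = 4.77e-12, adjusted p = 0.436 with an estimated correlation) and brown fat by 1.24 (adjusted p = 8.44e-08, adjusted p = 0.436 with an estimated correlation), in which Cox8b and Cox7a1 passed over the list alone, against 0 members of the mitochondrial lists. The adipocyte list rose by 0.67 (adjusted p = 0.000243, adjusted p = 0.671 with an estimated correlation), the endothelial list by 0.27 (adjusted p = 0.00264, adjusted p = 0.674 with an estimated correlation), each with 0 members over the list alone, and the skeletal muscle list by 6.72 (adjusted p = 1.09e-22, adjusted p = 0.386 with an estimated correlation), the last with 16 of 16 members. In 28-day replicate 3 alone it was 2.59 log2 above 14 days. The smallest p of the comparison belonged to Pde3a, a cyclic nucleotide phosphodiesterase, at 71.1 ± 17.3 and 32.3 ± 2.46 CPM (adjusted p = 0.770; Entrez 54611, chromosome 6, 141249269 to 141506862). Hbegf, Pi15 and F2r were lower by 1.25 ± 0.24, 1.76 ± 0.34 and 1.11 ± 0.22 log2, and Depp1 and Tbc1d4 were higher by 1.33 ± 0.25 and 0.82 ± 0.16.

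In all, 16 of 29 lists passed, 6 up and 10 down, and 0 with an estimated correlation (2 at an unadjusted p under 0.05) or by fry. Other splits of the same 6 libraries into 3 and 3 gave 8 to 22 lists. Over the lists alone 20 members passed, and 0 over all genes. edgeR called 0 genes, with 903 at an unadjusted p under 0.05 (569 up, 334 down) where chance gives 737 on average. Another split of the same 6 libraries gave 1765 such genes, more than the real groups did. DESeq2 called 126 (97 up, 29 down) and limma-voom 0. The groups did not overlap for 10.1% of genes, where chance gives 10%. Lists that did not pass were T cell (-0.74 log2, adjusted p = 0.116), B and plasma cell (0.51, 0.350), neutrophil (0.350), MHC class II (0.339), type I interferon (-0.25, 0.124), fibroblast (0.856), nerve (0.598), cartilage (0.252), immediate early (0.118), ER stress (0.331), renin-angiotensin (0.720), circadian clock (-0.01, 0.720, test direction up) and foam cell (0.696).

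Of these 16 calls, 8 held without each library in turn. The others did not pass without some library: smooth muscle without 14-day replicate 1 (-0.33, adjusted p = 0.229), elastic fibre without 28-day replicate 2 (-0.38, 0.0531), proteases without 14-day replicate 2 (-0.03, 0.948) or 28-day replicate 2 (-0.31, 0.178), adipocyte without 14-day replicate 2 (0.05, 0.380), and endothelial without 14-day replicate 2 (0.10, 0.120) or 28-day replicate 1 (0.00, 0.342). The macrophage list rose without 14-day replicate 2 (0.29, adjusted p = 0.0331) and did not pass without 28-day replicate 1 (-0.34, 0.197) or 28-day replicate 2 (-0.51, 0.0776). The inflammasome list failed without 14-day replicate 2 (-0.12, 0.80) or 28-day replicate 1 (-0.31, 0.182). Red cell genes failed without sham replicate 1 (-0.45, 0.0552), sham replicate 2 (-0.44, 0.0595), 14-day replicate 1 (-0.54, 0.0891), 14-day replicate 2 (-0.09, 0.80), 28-day replicate 2 (-0.31, 0.178) or 28-day replicate 3 (-0.43, 0.0584). Values that passed but moved were smooth muscle without 14-day replicate 2 (-1.47), 28-day replicate 1 (-1.31) or 28-day replicate 3 (-0.45), collagens without 14-day replicate 2 (-0.29) or 28-day replicate 2 (-0.44), and cell cycle without 14-day replicate 1 (-1.18), 14-day replicate 2 (-0.31) or 28-day replicate 1 (-0.38). Others were proteases without 14-day replicate 3 (-0.85), macrophage without 14-day replicate 1 (-0.92) or 3 (-0.96), inflammasome without 14-day replicate 1 (-0.82), red cell without 14-day replicate 3 (-0.70), endothelial without 14-day replicate 1 (0.46) or 28-day replicate 2 (0.40), and adipocyte without 14-day replicate 3 (1.06) or 28-day replicate 2 (1.01).

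Several lists passed between the times without 1 library. The T cell list fell without 14-day replicate 1 (-1.52, adjusted p = 0.00382), 14-day replicate 2 (-1.18, 0.0188) or 28-day replicate 2 (-1.56, 0.00113), and the B and plasma cell list rose without 14-day replicate 3 (1.93, 0.000291) or 28-day replicate 1 (1.54, 0.00101). MHC class II passed without 14-day replicate 1 (-0.61, 0.0413) or 28-day replicate 2 (-0.76, 0.00357), interferon without 14-day replicate 3 (-0.43, 0.0102) or 28-day replicate 3 (-0.57, 7.20e-05), and cartilage without the same libraries (-0.61, 0.0331, and -0.67, 0.0226). ER stress passed without 14-day replicate 3 (-0.25, 0.0227) or 28-day replicate 1 (-0.23, 0.0430), nerve without 28-day replicate 1 (2.18, 0.0123) and immediate early without 28-day replicate 2 (-0.38, 0.0338). Without the 3 nerve-rich libraries smooth muscle (-0.24, 0.604), elastic fibre (-0.46, 0.136), proteases (-0.50, 0.299) and red cell (-0.47, 0.369) did not pass, while T cell (-2.40, 0.000792), MHC class II (-1.28, 0.00101) and fibroblast (0.40, 0.0334) did. In that fit the values were -0.98 for NF-kB, -1.5 for cell cycle, -1.03 for inflammasome, -0.96 for macrophage, 1.16 for adipocyte and 0.52 for endothelial genes. The macrophage list also failed with the replicate block (adjusted p = 0.0571) and the nerve covariate (0.0747), and the red cell list with the block (0.0571) and with no filter (0.109), while interferon passed with the nerve covariate (0.0433). In 28-day replicate 3 alone (n = 1), the mean differences from 14 days were 0.01 for endothelial, -0.39 for inflammasome, -0.11 for macrophage, -0.76 for neutrophil, -0.49 for immediate early, 0.38 for interferon, -1.5 for smooth muscle, -0.46 for collagen and 1.07 for adipocyte genes.

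**Figure D3:**
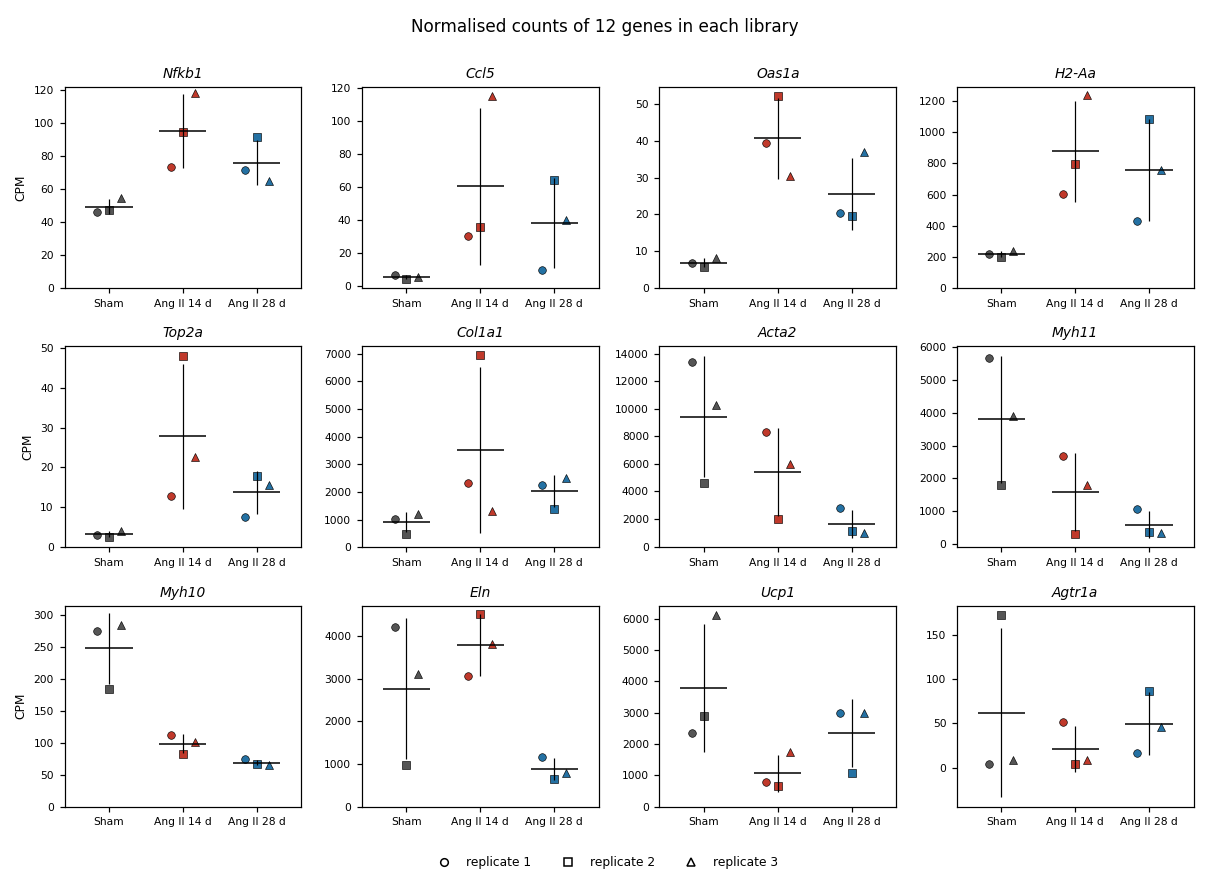
CPM of 12 genes in each of the 9 libraries, on linear axes, with the mean ± SD of 3 libraries per group. In the order sham, 14 days and 28 days, the Acta2 means are 9441, 5438 and 1631 and the Nfkb1 means are 49.3, 95.3 and 76.0.

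The changes at both times were set side by side to ask how far they are shared. edgeR called 0 genes at both times, and 1295 genes had an unadjusted p under 0.05 in the same direction at both (944 up, 351 down). DESeq2 called 566 at both times in the same direction, 470 up and 96 down, where independent lists of the same sizes give 50.6 and 17.0. Both comparisons use the same 3 sham libraries, which cannot be divided between them. Groups simulated without any change against the same sham libraries shared a median of 7 DESeq2 genes (range 3 to 10) and 159 at the unadjusted threshold. Across genes, which are not independent replicates, the log2 fold changes at 14 and 28 days correlated with r = 0.73, and with r = 0.51 (0.46 to 0.53) in the simulated groups. Their covariance was 0.793, and 0.258 in the simulated groups, a difference of 0.535. Real libraries of 1 group also share differences in the tissue they hold, which the simulated groups do not.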

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

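All tests of the patterns weighed here were chosen after the result was seen, while the comparison of 28 with 14 days was planned. By the test of the difference between the times itself, 16 of 29 lists passed, and their values are given below. Splits of the 14-day and 28-day libraries into 3 and 3 number 10. At least 16 lists passed in 3 of these splits, the real split included, and 22 passed in the highest other. The count of 16 lists therefore does not set the real grouping by time apart from other splits. Against 14 days, the mean log2 change at 28 days was -0.80 for contractile smooth muscle, -0.71 for fibrillar collagens and fibrotic matrix, -0.64 for elastic fibre, -0.50 for matrix proteases and inhibitors, -0.60 for NF-kB targets, -0.53 for macrophage and monocyte, -0.44 for red cell and platelet, -0.75 for cell cycle, -0.89 for TGF-beta and -0.51 for inflammasome genes. It was 0.27 for endothelial, 0.67 for adipocyte, 1.24 for brown fat, 6.72 for skeletal muscle, 0.87 for oxidative phosphorylation and 0.98 for fatty acid oxidation genes. With an estimated correlation 0 of these passed. The lists whose calls end without some library are named with the comparison. The lower mean of the smooth muscle list and the immune lists have no separate test of cause here, and the day of the sham aortas is not known.

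Nerve transcripts differed between libraries of 1 group by more than between groups, from 1.22 to 8.18 log2 CPM within sham. Infusion of Ang II is not needed for such a spread, since the sham libraries differed most. Their SD was 3.51, against 2.75 at 14 days and 2.64 at 28 days. All 6 Ang II libraries lay inside the range of the sham libraries. That range is so wide that an added effect of Ang II cannot be excluded. Without sham replicate 2 the nerve list was 1.96 log2 above sham at 14 days and 2.63 at 28 days. Adrenal medulla as the source is argued against by Pnmt, which makes adrenaline there, with 0.00675 counts per 100 counts of Th in the 3 libraries richest in nerve transcripts (2 against 29618 counts, upper 95% limit 0.0244). Sympathetic ganglion or nerve carried with the aorta may be the source, since 16 of 16 sympathetic neuron genes, Dbh and Th among them, correlated above 0.9 with the mean of the others, and 5 of the 16 are also in the fixed lists. How much nerve an aorta of this segment holds without any carried tissue stays open.

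The mean of the skeletal muscle list was higher in each 28-day library than in the other 6, and Acta1 reached 4696 CPM, although Ckm (36.5 against 13.3 CPM), Tnnt1 (8.95 against 0.683), Mybpc2 (5.22 against 0.835) and Mb (119 against 14.5), which is not in the list, were higher in sham replicate 1 than in 28-day replicate 3. Sham replicate 1 also held the heart muscle genes Myh6 and Tnnt2 at 324 and 171 CPM, while the fast-fibre genes Myh4 and Myh1 were at 0 and 0.213 CPM there. Skeletal muscle carried with the aorta is a candidate source, since 14 of the 16 members lay within 2-fold of 1 common ratio between replicates 1 and 2 (median log2 ratio 1.5), the exceptions being the slow-fibre genes Tnnt1 and Tnni1. A change in the aortic wall by 28 days was asked to leave the 28-day libraries no further apart than in other lists. The list lay at 9.21, 7.87 and 2.33 log2 CPM in these libraries. Its SD of 3.65 was the largest of the lists (2.64 for the nerve list, the next), which argues against a uniform change in the wall. A change that differs between libraries cannot be told apart from carried muscle. The lowest 28-day library lay 1.89 log2 CPM above the highest of the other 6, so the tissue goes with the group. The titles of all 9 samples name muscle and the tissue labels name aorta, so the titles do not separate the 28-day libraries from the others.

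Mitochondrial lists were lower at 14 days together with brown fat genes. A smaller share of brown fat in the 14-day libraries may account for most of it, since the difference of the oxidative phosphorylation list went from -1.19 ± 0.34 to -0.27 ± 0.26 (SE) with the level of 6 brown fat genes as a term, and that of fatty acid oxidation from -1.38 ± 0.40 to -0.29 ± 0.25. All 6 genes are also in the fixed lists. Their level was 7.31, 7.68 and 8.84 log2 CPM in sham replicates 1 to 3, and 6.04, 5.95 and 6.82 at 14 days. These levels did not overlap, so the term cannot be fully separated from the group. Over the 9 libraries those genes correlated with oxidative phosphorylation at r = 0.96 (exact permutation p = 9.92e-05, adjusted p = 0.000149 over 3 relations), rho = 0.92 (p = 0.00131), r = 0.94 without the 2 farthest libraries and r = 0.90 within groups (p = 0.0139), and with fatty acid oxidation at r = 0.97 (p = 8.27e-06, adjusted p = 2.48e-05), rho = 0.98 (p = 4.96e-05), 0.97 and 0.93 (p = 0.00463). Dilution of resident tissue by immune cells as the whole cause is argued against, since the endothelial and fibroblast lists changed by 1.42 ± 0.23 and 1.76 ± 0.24 log2 more than oxidative phosphorylation did, while the adipocyte and contractile smooth muscle lists, at -0.84 and -1.0 log2, fell with it, so that dilution as a part of the cause stays open. Lower activity of the brown fat itself under Ang II, and a difference in dissection, stay open.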

How the results depend on the processing

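The planned settings were fixed beforehand, and limma-voom, the nerve covariate, the unadjusted overlap and the fits without 2 muscle-rich or 3 nerve-rich libraries were chosen after the data had been seen. Since edgeR called no gene, there was no single-gene call to lose. Of 8134 single-gene values, 203 newly passed (199 under DESeq2) and 84 changed sign without passing in either. For lists, 1188 of 1479 kept both, 185 no longer passed, 54 newly passed, 49 changed sign without passing in either, and 3 passed with the other sign, 1 of them in a fit with 1 library at 28 days. The cause was not tested except where stated.

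Over all genes, edgeR called 0 in each comparison (3460, 2042 and 903 at an unadjusted p under 0.05) and limma-voom 0. DESeq2 called 1902, 996 and 126. At 14 days the replicate block called 1 (Plac8, 2.79 log2, adjusted p = 0.0459), and the fit of the 2 groups alone and the fit without the 2 muscle-rich libraries called 1 each (Marco, 7.15 and 7.14, adjusted p = 0.0288 and 0.0328, near 0 in sham, so that these folds are no bounds). For Plac8, Ang II 14 days against sham, adjusted p ran from 9.42e-12 by DESeq2 to 0.256 without sham replicate 3. Leaving out each library gave 0 to 0 genes at 14 days, 0 to 7 at 28 days and 0 to 0 for 28 against 14 days. Without sham replicate 2 there were 5, all lower (Ccdc42, Fbxo30, Igsf9, Itgb3 and Myh10, adjusted p = 0.0289; for Myh10, Ang II 28 days against sham, from 1.30e-13 by DESeq2 to 1 without the 2 muscle-rich libraries, which leaves 1 library at 28 days), and without 28-day replicate 3 there were 7, all higher, among them the muscle genes Actn3, Mylpf, Myoz1, Neb, Ryr1 and Tnni2 (adjusted p = 0.0356). For genes changed at both times the count was 0 by edgeR, 566 by DESeq2 and 1295 at an unadjusted p under 0.05, and 0 to 0 without each library. No pairing by replicate number was found, which does not exclude one. Of 9 pairs of the same number, 3 correlated above 0.1 after removal of group means (r from -0.55 to 0.65), and 3 libraries matched their own number best.

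The lists called were 20, 20 and 16. With an estimated correlation they were 0, 0 and 0, since each list then carries its own correlation, and by fry 10, 0 and 0. Leaving out each library gave 17 to 24, 16 to 20 and 12 to 20. In 28 against 14 days, 2 lists passed with the other sign, macrophage without 14-day replicate 2 (0.29, adjusted p = 0.0331, range without each library -0.96 to 0.29) and fibroblast, not called in the reported analysis, without the 3 nerve-rich libraries (0.40, adjusted p = 0.0334). Type I interferon, also not called, was at 0.38 log2 without the 2 muscle-rich libraries, a comparison of 1 library, 28-day replicate 3, from which no call is read. The limma fit to FPKM was not run.

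Splits of 6 libraries into 3 and 3 number 10 per comparison, too few for a share under 0.05. The real counts and the highest of the other splits were 0 and 0 by edgeR in all comparisons. By DESeq2 they were 1902 and 747 at 14 days, 996 and 1369 at 28 days, and 126 and 536 for 28 against 14 days. At an unadjusted p under 0.05 by edgeR they were 3460 and 2514, 2042 and 2544, and 903 and 1765. For lists they were 20 and 20, 20 and 17, and 16 and 22. The count of lists at 14 days was reached in 2 of the 10 splits, the real one included. The split with 1369 set sham replicates 1 and 3 and 28-day replicate 1 against the rest and follows the nerve level, which points to a structure of the samples. The split with 536, several times the real count, set 14-day replicate 1 and 28-day replicates 1 and 3 against the rest. It does not follow the nerve level (7.20, 2.22 and 6.24 against 1.70, 4.71 and 7.19 log2 CPM). What lies behind that split was not tested. For genes shared by both times, 100 of the 840 groupings of 9 libraries were drawn. The DESeq2 count of 566 was reached in 1 of 100, the real one, a share under 0.05 of those drawn. The highest other, 509, came from a grouping that keeps the 3 sham libraries together. Most of the 840 groupings were not drawn, so chance is made less likely for that count but is not excluded. By edgeR the real count was 0, which all 100 reach, so the groupings say nothing on it. The unadjusted count of 1295 was reached in 4 (highest other 1503). At these depths a count of 0 allows 0.204 to 0.328 CPM, so changes of genes under that level in both groups were not detectable. The self-test called 48% of the genes changed 4-fold at 14 days by edgeR.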

Other observations

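Apart from Agtr1a, the genes named here were picked after their values were seen, and so was the correlation of Agtr1a with the nerve list. DESeq2 and the adjustment over a list alone were planned. Transcripts of lymphoid follicles were high in 2 libraries. Cr2 and Fcer2a, complement and IgE receptors of B cells and follicular dendritic cells, had 37.6 and 149 CPM in 14-day replicate 3 and 69.4 and 125 CPM in 28-day replicate 2, and Cr2 stayed at 5.54 CPM or lower in the other 7. A list of 8 lymph node stroma and vessel genes, written after the data had been seen, had a level of 0.42, 0.17 and -0.04 log2 CPM in sham, 1.92, 0.88 and 4.42 at 14 days, and 2.70, 5.74 and 3.18 at 28 days. Glycam1, a ligand on high endothelial venules, had 248 CPM in 28-day replicate 2 and at most 33.0 CPM elsewhere. Marco, a scavenger receptor of macrophages, was at most 0.213 CPM in sham, 28.3, 19.0 and 18.5 CPM at 14 days, and 2.95, 358 and 22.8 CPM at 28 days. DESeq2 called it at both times (adjusted p = 2.09e-05 and 3.98e-10).

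Sost and Wif1, which encode secreted antagonists of Wnt signalling, were picked after their values were seen. Sost was 283 ± 153 CPM in sham, 82.7 ± 53.7 at 14 days and 15.7 ± 7.83 at 28 days (SD, 3 libraries each; DESeq2 adjusted p = 1.57e-07 for 28 days against sham; Entrez 74499, chromosome 11, 101962458 to 101967015). Wif1 was 14.2 ± 11.8, 2.75 ± 1.51 and 0.673 ± 0.310 CPM (DESeq2 adjusted p = 0.000229 at 28 days). Optc was lower by 3.55 ± 0.79 log2 at 28 days (SE; DESeq2 adjusted p = 0.000149). The heat-shock gene Hspa1a was 64.0 ± 17.8, 22.5 ± 10.3 and 18.4 ± 7.87 CPM, lower by 1.51 ± 0.44 and 1.79 ± 0.44 log2 (DESeq2 adjusted p = 0.0167 and 0.00590), and Hspa1b was lower by 1.5 ± 0.45 and 1.65 ± 0.46. Reads of Hspa1a and Hspa1b can match each other. Junb, an AP-1 factor, rose by 1.92 ± 0.46 log2 at 14 days over the immediate early list alone. Runx2, a factor of bone and cartilage cells, was 2.35 ± 0.67 log2 higher at 14 days. Comp, a cartilage matrix gene, was 3.37 ± 1.03 log2 higher, and Matn3, another, was 0.0831 ± 0.0895 CPM in sham and 1.36 ± 1.82 CPM at 14 days. Olr1, a receptor for oxidised LDL, was 3.08 ± 0.81 log2 higher. None of these passed over all genes by edgeR, whose counts by other tools are given with each comparison.

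Agtr1a levels followed the nerve list over the 9 libraries, with r = 0.86 (exact permutation p = 0.00652, adjusted p = 0.00652 over 3 relations), rho = 0.80 (p = 0.0138), r = 0.83 without the 2 farthest libraries and r = 0.89 within groups (p = 0.0185). The first principal component, with 42.5% of the variance, has nerve genes such as Dbh and Th at its high end. Many other genes may therefore follow the nerve list as closely. Their share was not computed, so the relation is not shown to be particular to Agtr1a. Heart muscle genes were high in sham replicate 1, where Myh6 had 324 CPM and Tnnt2 171 CPM, against at most 7.49 and 8.45 CPM elsewhere. Mb, myoglobin, had 119 CPM in the same library. Ren1 had 9.66 CPM in 14-day replicate 1 and at most 1.29 CPM elsewhere.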
